A study of Mus musculus with 2 samples.

How the data were processed

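Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in hematopoietic stem cells (HSCs) from mouse bone marrow. There were 2 samples, 1 from naive mice and 1 from C57BL/6J mice 6 weeks after infection with the bacterium Listeria monocytogenes (LM). The labels give an age of 6 to 8 weeks for the mice and a wild-type genotype for both samples. Whether this age holds at infection or at sampling is not settled here, so the ages of the groups at sampling may differ. The peak identifiers inside the LM-challenged list carry a knockout tag and those of the naive list a wild-type tag. The labels were followed here, and the origin of the tag is not given in the sources used here.

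The submitters' processing notes name Trim Galore, Bowtie2, deepTools and MACS2 and the mouse build mm10, without versions or settings. The deposited data are 1 peak list per sample, and nothing in the labels says that samples were pooled. Per the column order of the deposited lists, each peak has a position, a whole-number score, a fold enrichment (the ratio of the summit pileup to a local background, each plus 1), a −log10 p-value, a −log10 q-value and a summit position. The deposited score equals 10 times the −log10 q-value rounded down, apart from rounding. The fold, p and q values are the authors' own values for each peak within its list. Read counts and sequencing depth were not used here.

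The naive list held 57168 peaks over all chromosomes. The LM-challenged list held 229 records, all on chromosome 1, and ended inside a record. That last record had 6 filled fields of 10 and no fold, p-value, q-value or summit, so 228 records were complete. The list ended at position 24100766 of chromosome 1. Comparisons between the libraries were therefore restricted to chromosome 1 from position 1 to 24100766, called the stretch here. The rest of the LM-challenged library was not analysed here.

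The number of overlapping reads at each summit (the pileup) and the local background were recovered from the deposited fold and −log10 p-value. For a Poisson background, these values fix 1 whole-number pileup and 1 background. The recovered pair gave back the deposited −log10 p-value within 0.00016 in the naive list and within 2.6e-05 in the LM-challenged list, while the next best whole number missed by at least 0.0095 and 0.014. The lowest background in a list is its genome-wide level. It was 0.598 reads in the naive list and 0.533 reads in the LM-challenged list, a ratio of 0.891. All other backgrounds in both lists were whole multiples of 0.02 within a tolerance of 0.001. The ratio of the backgrounds stands for the ratio of the depths only if both calls used the same read extension and genome size, which the sources used here do not give. On simulated naive peaks with known pileups, all 2993 were recovered. An earlier form of the recovery did not give back the deposited p-values and was replaced, and no value given here comes from it.

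Peaks of the lists were compared by an overlap of at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, and random overlap was measured by placing the peaks of 1 list 1000 times at random positions in the stretch. At peaks paired uniquely between the lists, the ratio of LM-challenged to naive pileup was divided by the ratio of the backgrounds and given an exact conditional binomial 95% interval. Among 1598 simulated pairs without a change, 2.63% of the intervals excluded 1. Among 400 simulated pairs with a doubling, 53.5% lay above 1, and among the 125 of these with a naive pileup of at least 20, 78.4% did. Intervals cover counting error only. Reads are not independent molecules, summits are the highest points of peaks, and each group had 1 library, so no test between the conditions was possible and no p-value was computed. The recovery of pileups, the pairing of peaks, the scaling by the backgrounds, the restriction to the stretch and the limit of 20 reads were chosen after the data were seen.

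Genes were taken from the RefSeq table of GRCm38.p6, whose chromosome coordinates are those of mm10; genes on scaffolds were left out, which kept 21770 protein-coding and 12637 lncRNA genes. The table gives the start and end of a gene model but no strand and no single transcripts. The promoter window planned before the data were examined was therefore replaced by a window of 1000 bp around either end of the gene model, which includes 3′ ends and misses internal promoters. The motif comparison planned at the same time needed genome sequence and was not run. Of 335 genes on 13 lists fixed before the data were examined, 333 matched the table by symbol; Mx1 and Mx2 were not protein-coding there. Each list's count was set beside 10000 random lists of protein-coding genes of the same size.

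Genes were named by a rule fixed before the data were examined. It took list members with an LM-challenged peak near a gene end, the genes nearest to the 10 LM-challenged peaks of highest fold with a naive partner and the 10 without, the 10 naive peaks of highest fold near a gene end, and per list the 3 members of highest naive fold and up to 3, in alphabetical order, without a peak. Some genes that the rule takes are not reported here. Genes named outside that rule are marked. Alternatives fixed at the same time were a q-value under 0.01, a fold of at least 5, merging of overlapping records, an overlap of 50% of the smaller peak, summits inside peaks, 500 and 3000 bp windows, protein-coding genes only, gene bodies with 10 kb around them, main chromosomes only and a naive list of matched length. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.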

Results

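Accessible chromatin was mapped by ATAC-seq in bone marrow HSCs of naive mice and of mice infected with Listeria monocytogenes 6 weeks earlier, with 1 library per group. The comparison asked which accessible regions differ in HSCs after the infection. The labels give both samples as wild type, while the peak identifiers of the LM-challenged list carry a knockout tag, so a difference in genotype is not ruled out. The naive list held 57168 peaks covering 26839 kb, with a median width of 396 bp, a median fold enrichment of 6.31 and a median of 13 overlapping reads at the summit. The LM-challenged list held 229 peaks covering 112.5 kb, all on chromosome 1 before position 24100766, where the list broke off inside a record. In that stretch the naive list held 238 peaks covering 117.35 kb, and it held 3648 further peaks on chromosome 1 beyond it. All statements on the LM-challenged library below concern this stretch, and no replicate gives a spread for any value.

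**Figure D1:**
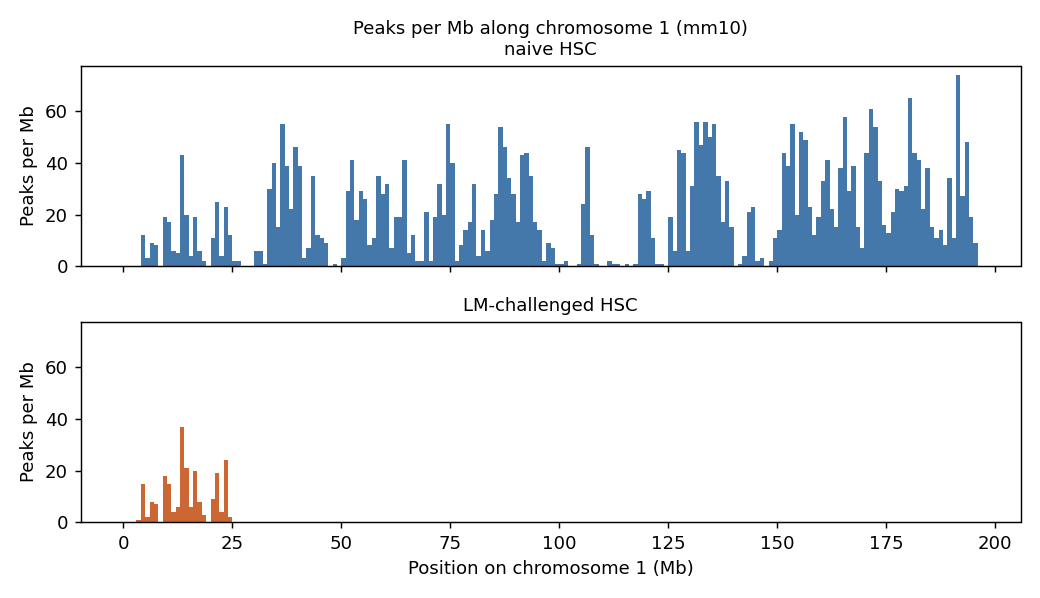
Number of peaks per Mb (vertical axis) along chromosome 1 in Mb (horizontal axis) in the naive (top) and the LM-challenged list (bottom). Naive peaks run along the whole chromosome, while the 229 LM-challenged peaks end at position 24100766.

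In naive HSCs, several of the 13 fixed lists had a peak near a gene end in a larger share than protein-coding genes at large. The housekeeping list had the highest share (94.4%). The cell cycle, interferon response, antigen presentation, immediate early, NF-kB and chromatin regulator lists were raised too. The raised share was therefore not particular to cell cycle and immune genes. The random gene lists given below were drawn from all protein-coding genes without matching. Lymphoid genes had the lowest share of the 13 lists in this window. That rank was lost when gene bodies and 10 kb around them were counted. Of all 21770 protein-coding genes, 12695 (58.3%) had a naive peak within 1000 bp of an end of the gene model. Among the cell cycle genes, 28 of 31 did (90.3%, 95% interval 74.2% to 97.96%). The highest folds stood at Ccna2 (19.2, cyclin A2), Mcm3 (17.96) and Mcm4 (17.1), the last pair being subunits of the replicative helicase, and Aurkb, Ccnd3 and Cdkn1a had none. Of 10000 random gene lists of the same size, 0.01% reached that count. Among the immediate early genes, 22 of 24 did, led by Nr4a2 (10.5), Klf4 (9.15) and Batf (8.80), with none at Egr2 and Maff, and 0.03% of random lists reached the count.

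Immune response genes carried naive peaks as well. Of the interferon response genes, 33 of 38 had one near a gene end (86.8%, 95% interval 71.9% to 95.6%), a count that 0.01% of random lists reached. The highest folds stood at Stat2 (19.2) and Irf9 (15.4), which encode parts of an interferon-activated transcription complex, and at the interferon receptor gene Ifnar1 (15.3). Gbp6, Iigp1 and Isg15 had none. Of the antigen presentation genes, 18 of 20 did (0.19% of random lists), led by Nlrc5 (12.6), the activator of class I genes, and by 1 peak of fold 11.4 between the neighbours Psmb9 and Tap1, which both count it. Ciita, the class II activator, and Tap2 had none. Of the NF-kB and innate sensing genes, 23 of 28 did (0.55% of random lists), led by the endotoxin receptor gene Tlr4 (15.3), Ripk2 (11.8) and Birc3 (11.7), with none at Ccl5, Il1b and Il1r1.

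The housekeeping list had 17 of 18 genes with a peak (94.4%, 0.02% of random lists), led by Hprt (17.0), Pgk1 (16.8) and Sdha (15.5), with none at Ywhaz. Of the chromatin regulators 23 of 28 had one (0.68% of random lists), led by the Polycomb gene Suz12 (15.9), Hdac1 (15.1) and Asxl1 (13.9), with none at Dnmt1, Dnmt3a and Kdm6a. Of the glycolysis genes 14 of 18 did (7.07% of random lists), led by Pgk1, Hk2 (14.6) and Pdk1 (14.2), with none at Aldoa, Hif1a and Hk1.

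Among lineage lists, HSC identity genes had the highest share, with 26 of 35 near a gene end (74.3%, 95% interval 56.7% to 87.5%, 3.81% of random lists). Among its members, Ctnnal1 had a fold of 14.1 and Erg of 11.8, and Esam, Eya1 and Fgd5 had none there. The T, NK and B lymphoid list had 11 of 27 (40.7%, 95% interval 22.4% to 61.2%), a count that 98.03% of random lists reached. Its highest folds stood at Cd3d (11.8), Ebf1 (9.07) and Prf1 (7.98), and Cd3e and Cd3g had none. The intervals of these 2 lists overlap, both include the 58.3% of all protein-coding genes, and 13 lists were compared in all. The myeloid list had 17 of 28 (47.64% of random lists reached it), led by Irf8 (11.9), Cx3cr1 (10.2) and Cebpa (10.1), with none at Camp, Cebpe and Csf2ra. The erythroid and megakaryocyte list had 13 of 23 (65.47%), led by the transferrin receptor gene Tfrc (13.2), Nfe2 (11.9) and Gp1ba (11.2), with none at Alas2, Gata1 and Gp1bb. The stromal and endothelial list, cells that a bone marrow sample could also hold, had 11 of 20 (69.91%), led by Kitl (11.3), Kdr (11.2) and Pdgfrb (7.50), with none at Bglap, Cdh5 and Col3a1.

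These counts miss promoters inside gene models. Without strand they also do not tell a promoter from a 3′ end, so peaks such as those at Cd3d and Kdr may stand at either. With gene bodies and 10 kb around them, 34 of 35 HSC identity genes and 27 of 28 myeloid genes had a peak. So did 21 of 23 erythroid and megakaryocyte genes, 22 of 27 lymphoid genes and 16 of 20 stromal genes. The lymphoid list was then no longer the lowest, but it stayed close to the stromal list and below the other lineage lists. Outside the lineage lists, all 28 chromatin regulators, 18 glycolysis, 20 antigen presentation, 28 NF-kB and 24 immediate early genes had a peak there. All 31 cell cycle genes, all 18 housekeeping genes and 37 of 38 interferon response genes did as well. Dnmt1, Hif1a, Ciita and Il1b, given above with none, thus lacked a peak only near their gene ends. The share of all protein-coding genes in this wider window is not given here, so these counts have no baseline.

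**Figure D2:**
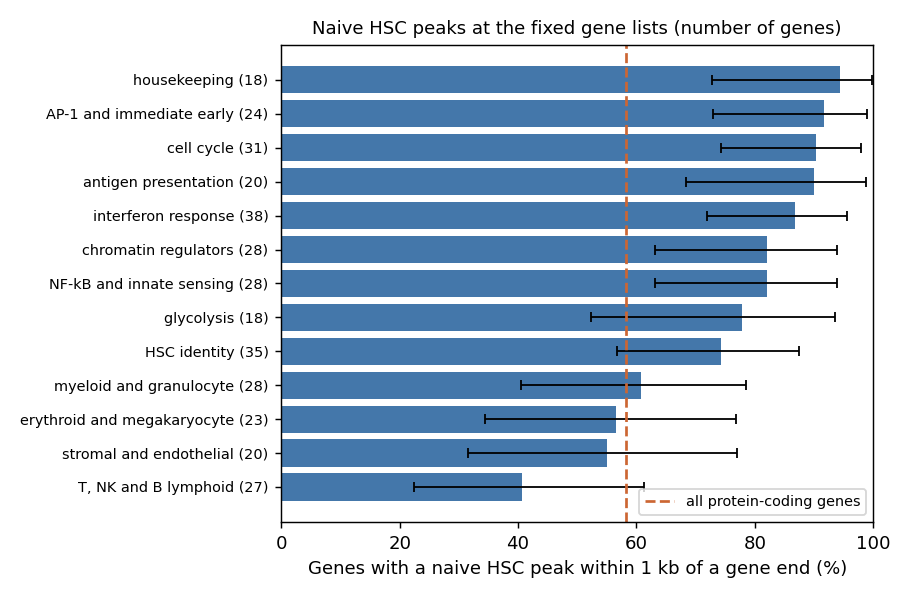
Share of the genes of each fixed list (rows, number of genes in brackets) with a naive HSC peak summit within 1 kb of an end of the gene model, in percent; lines are exact 95% binomial intervals and the dashed line marks all protein-coding genes (58.3%). The share runs from 40.7% in the lymphoid list to 94.4% in the housekeeping list.

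The naive peaks of highest fold near a protein-coding gene were at Gm20594 (22.9, chromosome 6, 79818000 to 79818388), Zfand1 (22.1, chromosome 3, 10351007 to 10351673) and Gins4 (21.5, chromosome 8, 23237270 to 23238016). Gins4 encodes a subunit of the replication complex GINS. Cpeb4 (21.4), Fggy (21.3), Taf6l (21.3), Tmem220 (21.2), Psmc4 (20.97), Alg10b (20.9) and Cbwd1 (20.9) followed. Over the numbered and sex chromosomes, 26.8% of naive summits lay near an end of a coding or lncRNA gene, 45.7% elsewhere inside a gene and 27.5% outside genes.

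In the stretch of chromosome 1 that both lists cover, most peaks of the LM-challenged and of the naive HSC library overlapped a peak of the other. Of the 229 LM-challenged peaks, 177 overlapped a naive peak (77.3%, 95% interval 71.3% to 82.6%), and of the 238 naive peaks, 181 overlapped an LM-challenged peak (76.1%, 70.1% to 81.3%). Random placement gave a median of 0.873% for the former and at most 3.49% in 1000 placements. Among peaks with at least 20 reads at the summit, 71 of 71 LM-challenged and 75 of 76 naive peaks had a partner, against 20 of 55 and 19 of 46 of those with 4 to 7 reads. The 52 LM-challenged peaks without a partner had a median of 6 reads at the summit and at most 14, and the 57 such naive peaks a median of 8 and at most 21. The peak with 21 reads lay near an end of Kcnq5, at 21963173 to 21963379, beside another peak that both lists held.

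**Figure D3:**
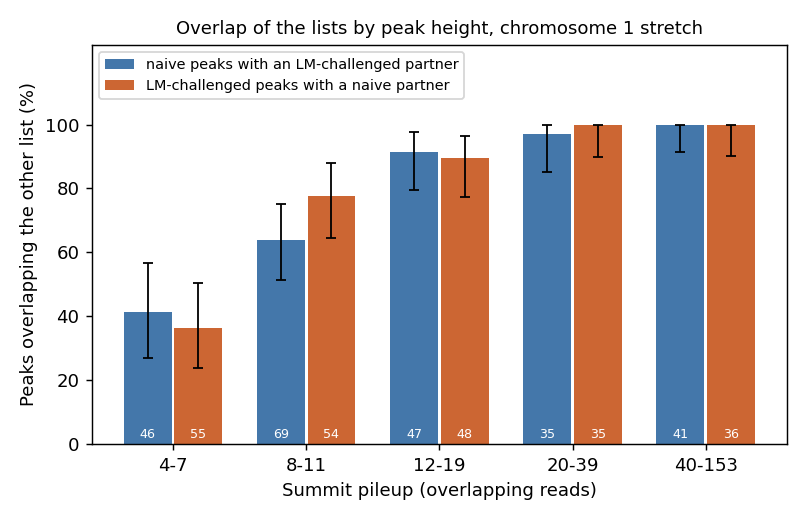
Share of peaks overlapping a peak of the other list (vertical axis, percent) by the number of overlapping reads at the summit (horizontal axis), for naive and LM-challenged peaks in the chromosome 1 stretch; lines are exact 95% binomial intervals and the numbers in the bars count peaks. The share rises from 41.3% and 36.4% at 4 to 7 reads to 41 of 41 naive and 36 of 36 LM-challenged peaks at 40 reads or more.

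In the stretch, 23.7% of LM-challenged summits (95% interval 18.3% to 29.7%) and 23.1% of naive summits (17.9% to 29.0%) lay near a gene end, against 2.44% of evenly spaced positions. Of the peaks with a partner, 28.4% of LM-challenged and 28.7% of naive summits were near a gene end. Of those without, 7.69% (2.14% to 18.5%) and 5.26% (1.10% to 14.6%) were. The peaks without a partner were also weaker, with medians of 6 (LM-challenged) and 8 (naive) reads against 16 and 15. Positions were not compared at matched reads, so peak height and position cannot be told apart here.

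Of the 80 protein-coding genes that end at least 1000 bp before the end of the stretch, 43 had a peak near a gene end in both lists, 32 in neither, 2 in the naive list alone and 3 in the LM-challenged list alone. The 2 were Rdh10, a retinol dehydrogenase gene, and Kcnq5, and the 3 were Xkr4, Ncoa2 and Kcnb2; all 5 were chosen after their values were seen. At Ncoa2, the LM-challenged peak at 13373934 to 13374581 lay inside the reach of a broader naive peak at 13372179 to 13374608 whose summit was farther from the gene end. At Rdh10, the naive peak at 16105688 to 16106323 had 44 reads and overlapped an LM-challenged peak whose summit lay outside the window. The peaks at Xkr4 and Kcnb2 had 5 and 6 reads at the summit. Only 2 genes of the fixed lists lay in the stretch, so no list could be compared between the libraries. Mcm3 had a peak near its end in both, and Eya1, a transcriptional coactivator gene of the HSC identity list, had none within the window in either. A peak of both lists lay just outside that window, 1172 bp from an end of Eya1.

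At sites found in both libraries, no scaled ratio of summit reads had an exact interval that excluded 1. Over 174 uniquely paired peaks, the median ratio of LM-challenged to naive summit reads, scaled by the background levels, was 1.12. Of the 174 intervals, 0 excluded 1, where up to 8.70 would by chance at the nominal level. Such intervals are wider than nominal, as only 2.63% excluded 1 among simulated pairs without a change. Without the scaling the median ratio was 0.995, so a general direction depends on the scaling. Unscaled, 2 of the 174 intervals excluded 1, both below it. Across peaks, which are not replicates, the log2 reads correlated with Pearson's r = 0.929 and Spearman's rho = 0.879. Summits of a pair lay a median of 25.5 bp apart. In the 61 pairs with at least 20 reads in both libraries, the ratio ran from 0.780 to 1.56, and for 46 of them the interval lay inside 0.5 to 2, so that a doubling or halving of reads was outside it. For weaker peaks a change of that size was often not detectable at this depth.

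**Figure D4:**
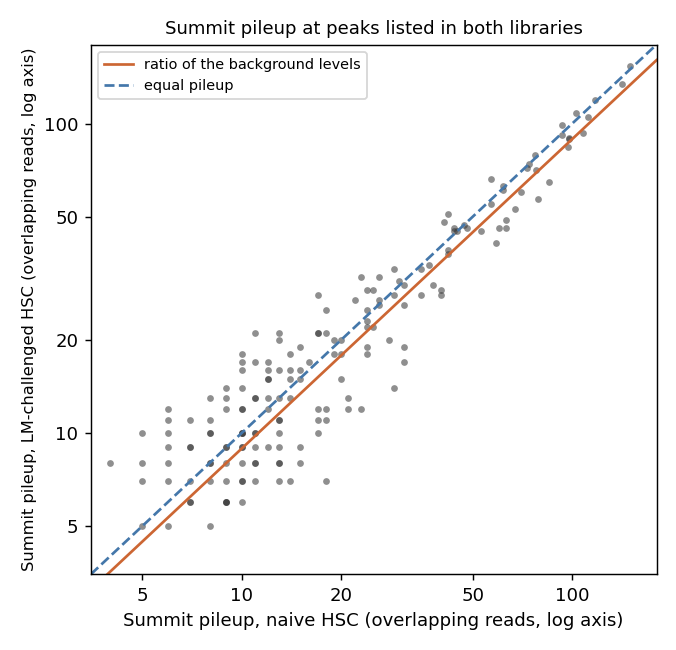
Overlapping reads at the summit of the 174 paired peaks in naive (horizontal axis) and LM-challenged HSCs (vertical axis), both on log axes; each point is a pair, the solid line is the ratio of the background levels and the dashed line equal reads. Points lie along both lines, with a wider scatter at low reads.

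The LM-challenged peaks of highest fold with a naive partner lay near a gene end in most cases, and gene functions were not tested. At Mcm3 (chromosome 1, 20819884 to 20820609) the fold was 18.2 in LM-challenged and 17.96 in naive HSCs, with 72 and 73 reads, a scaled ratio of 1.11 (95% interval 0.788 to 1.55). At Ube2w, a ubiquitin-conjugating enzyme gene (16618852 to 16619644), the folds were 18.1 and 14.9 and the ratio 1.15 (0.831 to 1.60). At Terf1, which encodes a telomere repeat binding factor (15805338 to 15806227), the folds were 17.5 and 18.6 and the ratio 1.11 (0.823 to 1.498). A further 6 had ratios between 0.967 and 1.17. They included peaks near an end of Tram2, of the mitochondrial ribosomal protein gene Mrpl15 and of the deubiquitinase gene Vcpip1, and inside Pcmtd1. The others lay outside genes, 50693 bp from Tram1 and 110195 bp from Ogfrl1.

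The 10 LM-challenged peaks of highest fold without a naive partner had lower folds. These folds ran from 5.87 to 8.48 and their summits held 8 to 14 reads. Those of highest fold were 88885 bp from Ly96 and 8414 bp from Crispld1, outside genes. The others lay 2953 bp from Sbspon, inside Kcnq5, Sgk3, Prdm14 and, at 2 places, Arfgef1, 13104 bp from Smap1 and 5581 bp from Eya1. The last of the 10, inside Arfgef1, was tied at a fold of 5.87 and 8 reads with 5 further peaks, of which 1 lay near a gene end, 211 bp from an end of Ube2w. The naive list shows only that no peak was called there.

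Genes of interest for infection or blood formation in the stretch were chosen after the values were seen, and none of the ratio intervals given here excluded 1. At Ly96, which encodes the Tlr4 coreceptor MD-2, the fold was 12.1 in LM-challenged and 11.4 in naive HSCs, with 39 and 42 reads (ratio 1.04, 95% interval 0.656 to 1.65). At Rb1cc1, an autophagy gene, 74 reads stood at the summit in both libraries (ratio 1.12, 0.802 to 1.57). At 1 end of Sox17, an endothelial and fetal blood stem cell factor, the reads were 28 and 17 (ratio 1.85, 0.977 to 3.60), and at the other end 34 and 29 (ratio 1.32, 0.778 to 2.24). Over the 5 paired peaks nearest to Sox17 the pooled ratio was 1.26 (0.952 to 1.66). The cytokine genes Il17a and Il17f had no peak near a gene end in either list.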

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

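The test for identical records and the pooled comparison near Eya1 were chosen after the data had been seen; the predictions of the other tests were written before their values were known. The idea of a truncated list came from seeing where the list ended, and the ratio of the backgrounds was already known when the test of depth was written. The naive list held 10 peaks on the unplaced contig JH584304, covering 4728 bp with up to 229 reads at a summit, outside every comparison of the report.

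The LM-challenged list is 229 records long against 57168. A truncated list is a candidate explanation, and a loss of accessible sites after infection another. Inside the stretch it covers, the list held 0.962 times as many peaks as the naive list, it stopped at position 24100766 of chromosome 1, and its last record is incomplete. These values go with a truncated list and against a loss of sites as the reason for its length. What the rest of that library holds stays open.

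Between the lists, 52 LM-challenged and 57 naive peaks had no partner. Of the 147 peaks with at least 20 reads at the summit in either list, 0.680% had none (95% interval 0.0172% to 3.73%). A site called in both lists counts once from each, so the peaks are not independent and this interval is too narrow. By list, 71 of 71 LM-challenged peaks (95% interval 94.9% to 100%) and 75 of 76 naive peaks (92.9% to 99.97%) had a partner. These shares go with a calling threshold that weak peaks pass in only 1 library. A lower depth of the LM-challenged library stays open as a contributor, since LM-challenged peaks made up 47.7% of those without a partner (38.1% to 57.5%), a share that includes an even split. A biological difference at such weak sites is not excluded by these values and was not tested, as each group had 1 library.

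At paired peaks the spread of the ratios was no larger than counting noise. The variance of the ratios in units of counting error was 0.711 (bootstrap 95% interval 0.582 to 0.840), and 0.523 among the pairs with at least 20 reads in both, below the value of 1 that independent Poisson counts would give. Pairs enter only if both libraries called a peak, and a summit is a maximum, which may narrow the spread; neither effect was measured. The identical set of reads, called the same way under both labels, is argued against. Of the 174 pairs, 0 had the same start, end and reads in both lists (upper limit 2.10%), and the backgrounds of the lists already differed. A subsample or a second sequencing of 1 library could differ in the same way, so the test cannot exclude shared material. Whether the libraries come from separate animals and separate preparations stays open, as do the knockout tag in the peak identifiers and a biological similarity of the samples, which was not tested.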

How the results depend on the processing

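No paired analysis was possible because each group held 1 library, and no replicate could be left out for the same reason. The motif comparison and its alternatives (50 bp around summits, a q-value under 0.01) were not run, since no genome sequence was used. Numbers of peaks stayed within 1.5 times the reported value in every alternative tried. The overlap shares stayed inside their intervals under a q-value under 0.01, a fold of at least 5, a 50% overlap, summits inside peaks, main chromosomes only, a naive list of matched length and, chosen after seeing the data, without the incomplete record. They moved, in an alternative chosen after seeing the data, to 100% of LM-challenged and 98.7% of naive peaks when only peaks with at least 20 reads were counted. The share of summits near a gene end moved by construction with the window. It was 21.7% at 500 bp, 37.9% at 3000 bp and 22.4% with protein-coding genes only in the whole naive list, and 30.7% at 3000 bp in both the naive and the LM-challenged stretch. The median log2 ratio at paired peaks, 0.16 with the background scaling, was -0.0078 unscaled and -2.1e-05 when scaled by its own median, both chosen after seeing the data, and 2 intervals excluded 1 under each instead of 0. The change in sign comes from the scale itself. Among the 13 gene lists, counts with gene bodies and 10 kb moved by more than 1.5 times in 3 and with a 3000 bp window in 1. Depth limits the comparison below about 20 reads at a summit, where simulated doublings were often missed.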

Other observations

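The comparison near Eya1 was chosen after the data had been seen. Eya1, a coactivator gene of the HSC identity list, had no peak within 1000 bp of its gene ends. A paired peak lay 1172 bp from 1 end, with 45 LM-challenged and 44 naive reads. With it, 11 paired peaks were nearest to Eya1, and 8 of them had a scaled ratio above 1. Their summit reads summed to 172 in LM-challenged and 147 in naive HSCs, a scaled ratio of 1.31 (95% interval 1.05 to 1.65). Among the 15 genes with at least 4 paired peaks, this was the only one whose interval excluded 1. That interval included 1.12, the median ratio of all paired peaks, so the peaks near Eya1 did not stand apart from the typical paired peak. Widened for 15 genes, the interval ran from 0.939 to 1.84, which decides nothing further about counting noise among many loci. Unscaled, the ratio was 1.17 (0.933 to 1.47) and its interval included 1.

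The lowest pooled ratio among these genes was 0.909 at B3gat2 (0.650 to 1.27). The lowest ratio among the 174 paired peaks, also picked after its value was seen, was 6165 bp from Defb41, with 7 LM-challenged and 18 naive reads (ratio 0.437, 0.154 to 1.10).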
